A study of Homo sapiens with 35 samples.

How the data were processed

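RNA of the SUM149 human breast cancer cell line was measured on Affymetrix human transcriptome arrays in 35 samples. Per the labels, the samples form 12 groups: DMSO, IR, PP242, RAD001, PP242 with IR and RAD001 with IR, each as RNA from polysomes and as total RNA. The labels give no dose, no time and no definition of IR, which is read here as ionizing radiation. Their growth and extraction protocols describe mouse forelimbs, which is at odds with the cell line, and were not used. The titles call the replicates biological but do not say that they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

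The deposited table holds log2 values for 65029 probe sets, a scale inferred from the values, since nothing in the sources used here states it. Values ran from 1.85 to 19.9 and array medians from 4.2 to 4.84. The highest values lie above what a scanner of 16 bits gives directly. The background correction, the normalization and any centring are not given in the sources used here. No genome build is named, so no coordinates are given. For arrays only their number limits the precision stated here.

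Probe sets were named through the platform annotation table: 23077 carried 1 gene symbol, 1357 carried several and 40595 had none in that table. Symbols were updated through gene identifiers. For each symbol the probe set with the highest mean was kept, which left 22384 genes, 17068 of them protein-coding; 421 genes had more than 1 probe set. Probe sets with several symbols were not named. No values were missing.

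Differential expression was tested on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). All 35 arrays entered 1 fit of 12 group means, so every comparison shares 1 estimate of the spread, with 23 residual and 2.69 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of single genes below come from this limma fit, and ± after a log2 change is its standard error. Translational efficiency is the change in polysome RNA minus the change in total RNA, tested as an interaction term. There were 27 comparisons: 15 against DMSO as the series' design text names them (5 treatments in polysome RNA, total RNA and translational efficiency), 8 between treatments, and 4 interactions of IR with an inhibitor. The design text names limma with p under 0.05 and a log fold change over 1.5; that threshold was run as an alternative.

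Gene groups were tested with camera (limma) at a preset correlation of 0.01, adjusted over 375 tests of 25 lists in the 15 comparisons with DMSO. List tests of the 12 other comparisons were added after the data were seen and adjusted over 300 tests. The lists, with measured members, were cytosolic ribosomal proteins (48), other 5' TOP mRNAs (23), ribosome biogenesis (41), ATF4 targets and amino acid supply (38), sterol and fatty acid synthesis (27), replication-dependent histones (23), DNA replication (53), mitosis and G2/M (51), DNA damage checkpoint signalling (39), homologous recombination and Fanconi anaemia (42), other DNA repair (43), p53 targets (31), apoptosis regulators (33), NF-kB and inflammatory (34), interferon response (39), immediate early genes (34), FOXO targets and receptor feedback (31), glycolysis and hypoxia (38), oxidative phosphorylation and mitochondrial ribosome (64), unfolded protein response and chaperones (31), lysosome and autophagy (37), nuclear-retained RNAs (10), and fibroblast (14), leukocyte (15) and endothelial (12) markers. Of 79 ribosomal proteins, 21 share a probe set with another gene and 10 were not named by the table. A list is called at an adjusted p under 0.05. Camera with a correlation estimated from the data and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. Of 375 tests, 144 were called with the preset correlation, 0 with an estimated correlation and 0 with fry. The smallest adjusted p was 0.653 with either. Which called lists are described was chosen after their values were seen. Described are 85 of the 144 calls against DMSO and 17 of 91 in the other comparisons; medians of those left out ran from -0.37 to 0.44 and from -0.89 to 0.45.

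The 27 comparisons of genes, the lists, their tests against DMSO, the alternatives not named as added and the rule for named genes were chosen before the data were examined. The rule takes, for each treatment against DMSO, the 6 largest rises and 6 largest falls in polysome RNA, 4 and 4 in total RNA and 3 and 3 in translational efficiency. It draws from genes past the threshold whose treated arrays all lie beyond all DMSO arrays, and passes over symbols that are not protein-coding, clone-like symbols, olfactory receptors, pseudogenes, Y-linked genes and XIST. It adds up to 4 members past the threshold per list, with p adjusted over the list alone, and for the other comparisons the 3 largest changes each way. Where none passed, up to 2 of the genes it draws from with the lowest p are given as values. Genes chosen after their values were seen are marked as such.

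Alternatives were every probe set, only the arrays of the groups compared, leaving out each array in turn, array weights, a filter at the 30th percentile of mean level, the replicate number as a block, quantile normalization within each RNA fraction and the design text's threshold. Added after the data were seen were fits without 8 arrays that stand apart, and with a batch term for them (1 per RNA fraction). Where PP242 with IR total RNA keeps 1 array, it is assumed to vary like the other groups. The limma step was tested on simulated data for PP242 against DMSO with 22384 genes. In polysome RNA it recovered 63 of 100 genes changed by 1 log2 unit and 95 of 100 changed by 2 units, and 15 of 173 calls were unchanged genes. For translational efficiency these were 52 of 100, 91 of 100 and 15 of 158. Camera with both correlations called a ribosomal protein list shifted by -0.5 and 0 others. With an estimated one it called 0 real lists, so the simulation may not hold for these arrays. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.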

Results

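SUM149 is a human cell line from an inflammatory, triple-negative breast cancer. PP242 blocks the kinase site of mTOR and so both of its complexes, and RAD001 (everolimus), a rapamycin analog, acts on the first of them. The arrays measured RNA bound to polysomes, the pool under translation, and total RNA after DMSO, IR, either inhibitor, or an inhibitor with IR. Each treatment was compared with DMSO in polysome RNA, in total RNA and in translational efficiency. There were 35 arrays in 12 groups of 3, except PP242 with IR in total RNA with 2. Levels are the deposited log2 values.

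The arrays did not group by treatment alone. In 8 arrays, genes of the cell cycle were lower and sterol synthesis genes higher than in the other arrays of the same groups. The 8 were replicate 3 of every inhibitor group, with or without IR, in polysome RNA and in total RNA, and replicate 2 of PP242 with IR in total RNA. No DMSO or IR array was among them. Below, DMSO 1 is replicate 1 of DMSO, replicate numbers without a name are those of the inhibitor with IR, and PP242+IR is PP242 with IR. The median of the DNA replication genes was lower in each of the 8, by -1.54 to -1.05 on the log2 scale against the remaining arrays of the group, and that of mitosis genes by -1.47 to -0.67. Replication-dependent histones differed by -1.50 to -0.76, sterol and fatty acid synthesis genes by 0.60 to 1.14 and immediate early genes by 0.31 to 0.93. In polysome RNA, MCM5 of the replicative helicase stood at 7.59 to 8.11 in 4 of these arrays and at 10.34 to 11.30 in the other 14, and fatty acid synthase FASN at 15.47 to 15.92 against 11.39 to 12.94. Markers of fibroblasts, leukocytes and endothelium were called in none of the 15 comparisons with DMSO, and their medians in the 8 arrays differed by at most 0.22 above the rest. Values without these 8 stand beside results they move. When only the arrays of the groups compared entered the limma fit, 0 genes passed in every comparison, so each count below rests on a spread shared by all 12 groups.

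**Figure D1:**
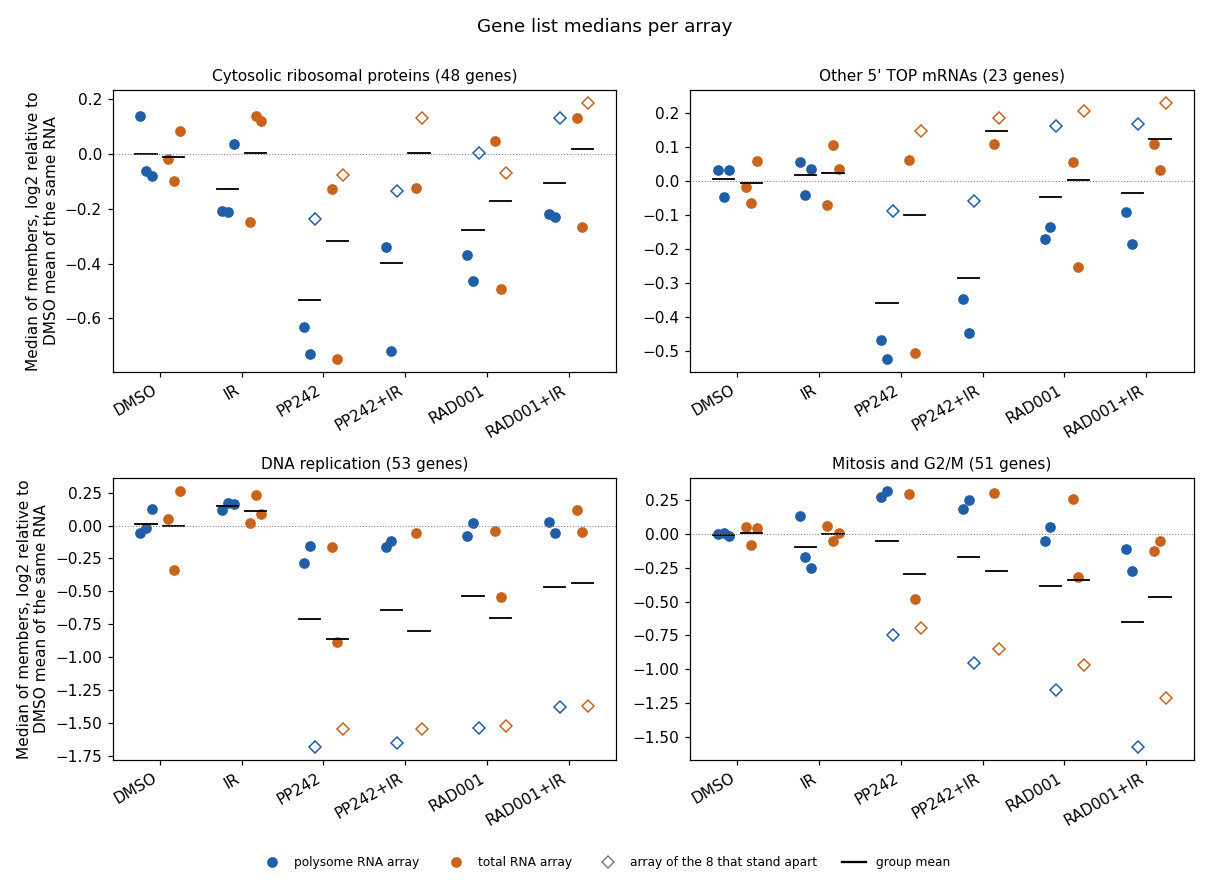
Median over the measured members of 4 gene groups in each array, as log2 relative to the DMSO mean of the same RNA, with polysome RNA in blue, total RNA in orange, bars for group means of the array medians and diamonds for the 8 arrays. DNA replication and mitosis genes lay lower in the diamonds.

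With IR alone, the question was which messages change in level or in polysome loading. No gene passed the threshold. Where none passed, lowest p means lowest among the protein-coding genes that the naming rule draws from. In polysome RNA it belonged to the linker histone H1-3, at 4.72 ± 0.11 (SD, n = 3) against 6.03 ± 0.22 in DMSO, a difference of -1.32 ± 0.43 (limma adjusted p = 1), and to AKAIN1, at 0.46 ± 0.15. Replication-dependent histones, which package new DNA and cross-hybridise within the family, had all 23 measured members below 0 and a median of -0.28 (camera adjusted p = 3.85e-05). Ribosomal protein mRNAs had 45 of 48 members below 0 (median -0.13, adjusted p = 9.99e-05), and oxidative phosphorylation (OXPHOS) and mitochondrial ribosome genes 49 of 64 (median -0.13, adjusted p = 0.000305). At an estimated correlation these adjusted p were 0.945, 0.999 and 0.945, so no list held. Left-out arrays moved ribosomal proteins to -0.05 and -0.20 (DMSO replicates 1 and 3) and to -0.08 and -0.22 (IR 1 and 3), and OXPHOS genes to -0.07 (IR 1), all called. Within the lists, 0 genes passed whether adjusted over all genes or adjusted over the list alone.

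Other shifts after IR in polysome RNA were called for ribosome biogenesis (median 0.13, 34 of 41 above 0, adjusted p = 0.00323), apoptosis regulators (-0.12, adjusted p = 0.0158) and nuclear-retained RNAs (-0.27, adjusted p = 0.0231). Under an estimated correlation their adjusted p were 0.945, 0.945 and 0.875. The ribosome biogenesis call ended without DMSO 1 (0.06) or IR 1 (0.08). The call of apoptosis regulators ended without DMSO 2 (-0.09), IR 1 (-0.08) or IR 2 (-0.10), and under quantile normalization. That of nuclear-retained RNAs ended without DMSO 1 (-0.21) or 3 (-0.27), or IR 1 (-0.19) or 2 (-0.20). Ribosome biogenesis stood at 0.08 without IR 3 and apoptosis regulators at -0.07 without DMSO 1, both called.

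In total RNA after IR, homologous recombination and Fanconi anaemia genes, which repair broken and cross-linked DNA, had 34 of 42 members above 0 with a median of 0.10 (camera adjusted p = 0.0272). The NF-kB and inflammatory list had 25 of 34 above 0 and a median of 0.08 (adjusted p = 0.0355). Given an estimated correlation the adjusted p were 0.999 and 0.945, and both calls ended under quantile normalization, with the low-level filter and when adjusted over the 25 lists of this comparison. The recombination call also ended without IR 1 (0.09) or 2 (0.06) or DMSO 1 (0.07) or 2 (0.01), and the NF-kB call without IR 1 (0.00) or 2 (0.06) or DMSO 2 (0.03) or 3 (-0.01); it stood at 0.17 and 0.20 without IR 3 or DMSO 1, called. Lowest p in total RNA were those of GNMT at -0.39 ± 0.11 and TAAR1 at -0.68 ± 0.20, and in translational efficiency those of TAAR1 at 1.25 ± 0.29 and RTL1 at 0.52 ± 0.16 (limma adjusted p = 1 for each, n = 3 per group). The p53 target list was not called after IR, and CDKN1A, an inhibitor of cyclin-dependent kinases chosen after its values were seen, was at 7.65 ± 0.13 in polysome RNA after IR and 7.88 ± 0.35 after DMSO (n = 3 each). By limma, 0 genes passed in polysome RNA, total RNA or translational efficiency, and 181, 171 and 197 had an unadjusted p under 0.05. With array weights, 3 genes passed in total RNA.

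For translational efficiency after IR, all 23 histones lay below 0 with a median of -0.32 (camera adjusted p = 0.00106). OXPHOS genes stood at -0.15 (adjusted p = 0.00387), apoptosis regulators at -0.13 (adjusted p = 0.00563) and ribosomal proteins at -0.11 (adjusted p = 0.00924). Using an estimated correlation the adjusted p ran from 0.945 to 0.999. Without IR total 3 or DMSO total 2 the histones stood at -0.22 and were not called. Without IR total 2 the medians of OXPHOS genes, apoptosis regulators and ribosomal proteins were 0.01, -0.06 and -0.01, and without DMSO total 2 they were -0.05, -0.04 and -0.10, none of them called. OXPHOS genes also lost the call without IR polysome 1 (-0.08) or IR total 3 (-0.11). Ribosomal proteins lost it without IR total 3 (-0.08), DMSO polysome 1 (-0.03), or IR polysome 1 (-0.08) or 2 (-0.07). Under quantile normalization only the histone list was called among these 4, and the low-level filter ended the ribosomal protein and OXPHOS calls. Among kept calls, histones stood at -0.55 without IR total 2 and OXPHOS genes at -0.28 without IR total 1 and -0.09 without DMSO polysome 1. Ribosomal proteins stood at -0.26, -0.20, -0.19 and -0.18 without IR total 1, IR polysome 3, DMSO polysome 3 or DMSO total 3.

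PP242 alone addressed which messages change when both mTOR complexes are blocked. Among genes past the threshold in polysome RNA, the largest fall was in ID3, an inhibitor of basic helix-loop-helix factors and a target of BMP signalling, at 5.82 ± 0.36 (SD, n = 3) against 8.45 ± 0.40 in DMSO, or -2.63 ± 0.40 on the log2 scale (limma adjusted p = 0.00312). SMAD6 and SMAD7, feedback inhibitors of BMP and TGF-beta signalling, fell by 1.64 ± 0.29 and 1.47 ± 0.27, and the endothelin EDN2 fell by 1.73 ± 0.29. The co-chaperone BAG2 and the transcription factor FOXI1 fell by 1.46 ± 0.31 and 1.43 ± 0.29. Their adjusted p ran from 0.00689 to 0.0315. Of genes chosen after their values were seen, the ubiquitin ligase SIAH2 had the smallest adjusted p, 7.33e-05, at -1.02 ± 0.12. The TGF-beta feedback genes SKIL and PMEPA1 stood at -1.16 ± 0.16 (adjusted p = 0.00107) and -1.35 ± 0.21 (adjusted p = 0.00312). ID1, a relative of ID3, was at 7.30 ± 1.55 against 11.32 ± 0.16 and did not pass (adjusted p = 0.0635).

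Among genes that passed and that the naming rule draws from, the largest rises with PP242 in polysome RNA were in the endothelial lipase LIPG (1.94 ± 0.38), the serine/threonine kinases PIM1 (1.82 ± 0.37) and PIM3 (1.09 ± 0.21), the mucosal glycoprotein DMBT1 (1.29 ± 0.25), IRAK2, a kinase of interleukin-1 and Toll-like receptor signalling (1.11 ± 0.19), and the ephrin EFNA1 (0.91 ± 0.16). Limma adjusted p ran from 0.00689 to 0.0268, and all 3 treated arrays lay above all 3 DMSO arrays for each. HBP1, a transcriptional repressor induced by FOXO factors, rose by 1.64 ± 0.25 (adjusted p = 0.00312); it was chosen after its values were seen, since its symbol ends like that of a pseudogene. In all, 60 genes passed, 12 higher and 48 lower. Under quantile normalization 85 passed, 49 higher and 36 lower, so the balance of directions depends on the scaling. The count was 17, 26 and 31 without DMSO 1, 2 or 3 and 23, 7 and 32 without PP242 1, 2 or 3. ID3 was called with each array left out. FOXI1, LIPG, PIM1, DMBT1 and PIM3 did not pass without the 8 arrays, at -1.38, 1.79, 1.66, 1.25 and 0.99. With 1 array left out in turn, BAG2 (-1.61 to -1.31) and PIM1 (1.66 to 1.92) lost the call 6 times of 6, FOXI1 (-1.60 to -1.31) with every array but DMSO 1 and LIPG (1.74 to 2.06) with every array but DMSO 2. SMAD7 (-1.60 to -1.37) lost it without DMSO 1 or 3 or PP242 1 or 3, DMBT1 (1.09 to 1.57) and PIM3 (0.96 to 1.32) without DMSO 1 or 3 or PP242 2 or 3, and SMAD6 (-1.77 to -1.51) without DMSO 1 or 3 or PP242 2. EDN2 (-1.92 to -1.34) lost it without DMSO 2 or PP242 2, and IRAK2 (1.00 to 1.25) and EFNA1 (0.79 to 0.97) without DMSO 3 or PP242 2. Quantile normalization ended the call of BAG2.

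**Figure D2:**
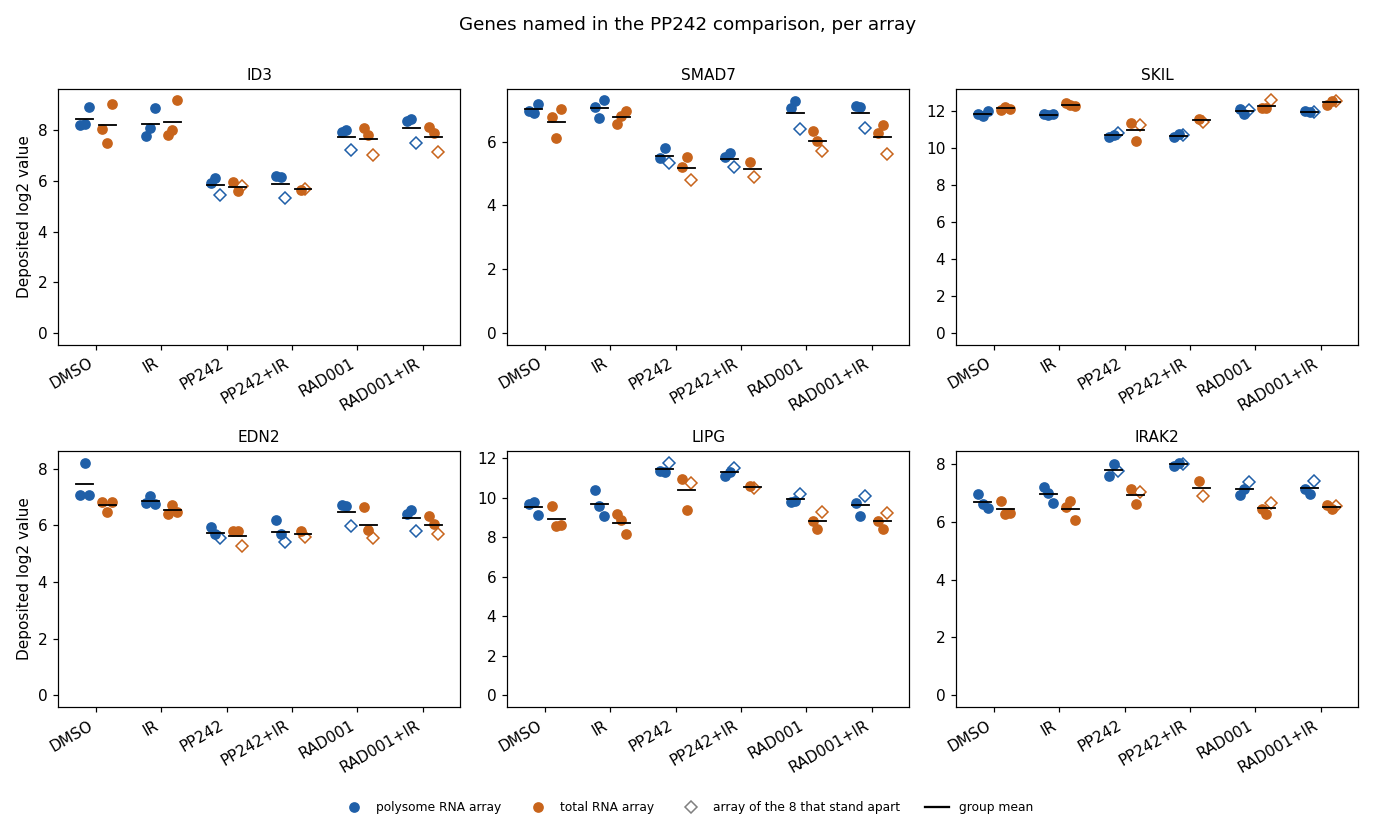
Deposited log2 value in each array for ID3, SMAD7, SKIL, EDN2, LIPG and IRAK2 by treatment, with polysome and total RNA in separate colours, bars for group means and diamonds for the 8 arrays. ID3 averaged 5.82 with PP242 and 8.45 with DMSO in polysome RNA.

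Messages of the translation machinery were lower on polysomes with PP242. Of 48 ribosomal protein mRNAs, which carry a 5' terminal oligopyrimidine (TOP) tract and cross-hybridise with pseudogenes, 47 lay below 0 and the median was -0.53 (camera adjusted p = 7.27e-30). Of them 3 passed over all genes, RPS21 (-0.86 ± 0.18), RPS7 (-0.64 ± 0.12) and RPL19 (-0.48 ± 0.10), and 30 passed adjusted over the list alone, all lower. RPS19, at -1.29 ± 0.40, was among them. Of 23 other TOP mRNAs 22 lay below 0 (median -0.32, adjusted p = 7.36e-10). The initiation factor subunit EIF2S3 (-0.89 ± 0.15, limma adjusted p = 0.00689) and the elongation factor subunit EEF1D (-0.39 ± 0.07) passed over all genes, and 5 fell adjusted over the list alone, among them NAP1L1 (-0.65) and EIF3H (-0.56). With an estimated correlation the adjusted p of the lists were 0.653 and 0.834. Both lists were called with each array left out, at -0.67 to -0.44 and -0.48 to -0.29 (-0.48 without PP242 3). RPS21 did not pass without the 8 arrays (-0.99), and of these genes EIF2S3 lost the call without PP242 2 (-0.78), RPS7 (-0.68 to -0.57) without DMSO 1 or PP242 1 or 2, RPS21 (-0.99 to -0.76) without those or DMSO 2, and RPL19 (-0.56 to -0.42) and EEF1D (-0.44 to -0.33) without any array but PP242 3 and under quantile normalization.

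Genes of DNA replication and repair were lower with PP242 in polysome RNA, and the groups moved with the 8 arrays. DNA replication genes had 49 of 53 members below 0 with a median of -0.75 (camera adjusted p = 5.07e-08), histones a median of -0.61 (adjusted p = 0.00014), checkpoint genes -0.33 (adjusted p = 0.00394), recombination genes -0.27 (adjusted p = 7.28e-05) and other DNA repair genes -0.29 (adjusted p = 1.57e-05). At an estimated correlation the adjusted p ran from 0.923 to 0.999. Over all genes 0 members passed in any of these lists. Adjusted over the list alone, 5 checkpoint genes fell and 2 rose, among them the phosphatases CDC25A (-1.58 ± 0.56), which drives entry into S phase, and PPM1D (-0.73 ± 0.20), the fork protein TIPIN (-1.49 ± 0.50) and the ubiquitin ligase RNF8 (-0.70 ± 0.20). Without PP242 3, which is among the 8 arrays, DNA replication stood at -0.20, histones at -0.25, checkpoint genes at -0.09 and recombination genes at -0.16, none of them called. Without all 8 arrays DNA replication genes (-0.20, adjusted p = 0.000406), histones (-0.25) and recombination genes were called and checkpoint genes (-0.09) were not. Histones stood at -0.94 without PP242 1 and other DNA repair genes at -0.17 without PP242 3, both called. Checkpoint genes also lost the call under quantile normalization and with the low-level filter.

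Other groups rose with PP242 in polysome RNA. FOXO targets and receptor feedback genes, held down by AKT when it is active, had 27 of 31 members above 0 with a median of 0.35 (camera adjusted p = 4.35e-06). Adjusted over the list alone, the ubiquitin ligase adaptor KLHL24 (1.18 ± 0.27), the mTORC2 subunit RICTOR (0.67 ± 0.21) and the cyclin CCNG2 (0.52 ± 0.13) rose and the sestrin SESN1 fell (-0.41 ± 0.11), while 0 passed over all genes. NF-kB and inflammatory genes had a median of 0.12 (adjusted p = 0.000264), and adjusted over the list alone the cytokine LIF rose, at 10.10 ± 0.90 against 6.96 ± 0.65 (SD, n = 3). Immediate early genes stood at 0.40 (adjusted p = 1.62e-05), sterol and fatty acid synthesis at 0.45 (adjusted p = 0.00127) and lysosome and autophagy genes at 0.10 (adjusted p = 0.0416). Under an estimated correlation the adjusted p ran from 0.653 to 0.990. Immediate early and sterol genes moved with the 8 arrays: without PP242 3 they stood at 0.10 and 0.07 and were not called. The sterol call also ended without DMSO 1 (0.36), and the lysosome call without DMSO 1 (0.14) or 3 (0.09) or PP242 1 (0.04) or 2 (0.11). FOXO targets stood at 0.19 without PP242 3 or without the 8 arrays, NF-kB genes at 0.19 without DMSO 1 and sterol genes at 0.75 without PP242 1, all called.

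Lower in the same RNA were OXPHOS genes (median -0.17, 50 of 64 below 0, camera adjusted p = 0.000481), interferon response genes (-0.24, adjusted p = 0.00106) and ribosome biogenesis genes (-0.14, adjusted p = 0.0296). Given an estimated correlation the adjusted p were 0.951, 0.923 and 0.999. The interferon-induced protease USP18 fell adjusted over the list alone (-0.62 ± 0.16), and the glycolytic regulator PFKFB3 fell over all genes (-0.76 ± 0.16, limma adjusted p = 0.0397) in a glycolysis list that was not called. The interferon call ended without PP242 3 (-0.12) and stood at -0.13 without DMSO 1, OXPHOS genes stood at -0.27 without PP242 3, called, and the ribosome biogenesis call ended without DMSO 3 (-0.05) or PP242 1 (-0.13) and with the low-level filter. Under quantile normalization the OXPHOS and ribosome biogenesis calls ended, as did that of PFKFB3, which also lost it without each of the 6 arrays in turn (-0.85 to -0.69) and without the 8 (-0.80). Members of the unfolded protein response and p53 lists passed adjusted over the list alone, namely the stress sensor ERN1 (0.91 ± 0.21) and PPM1D and SESN1.

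In total RNA, PP242 lowered ID3 by -2.41 ± 0.40 (5.78 ± 0.17 against 8.19 ± 0.77, SD, n = 3; limma adjusted p = 0.00844), and SMAD7 and PMEPA1 by -1.45 ± 0.27 and -1.25 ± 0.21. TACO1, a translational activator of a mitochondrial cytochrome oxidase subunit, fell by 1.45 ± 0.19 (adjusted p = 0.00126), and MRTO4, a ribosome assembly factor, fell by 0.88 ± 0.15. CCNG2 rose by 0.83 ± 0.13 (adjusted p = 0.00364) and the zinc finger protein ZBTB10 by 0.91 ± 0.18. The other 2 of the 4 genes higher, chosen after their values were seen, were HBP1 (1.37 ± 0.25) and the antisense transcript NOP14-AS1 (0.79). In all 28 genes passed, 4 higher and 24 lower; under quantile normalization 86 passed, 31 higher and 55 lower. Without DMSO 1, 2 or 3 the count was 18, 57 and 2, and without PP242 1, 2 or 3 it was 300, 22 and 9. TACO1 kept its call with each array left out. CCNG2 (0.78) and ID3 (-1.99) lost it without DMSO 3, PMEPA1 without DMSO 3 (-1.23) or PP242 3 (-1.15), SMAD7 (-1.71 to -1.25) without those or DMSO 1, MRTO4 (-1.04 to -0.74) without DMSO 1 or 3 or PP242 2 or 3, and ZBTB10 (0.72 to 1.11) without DMSO 2 or 3 or PP242 1 or 3. MRTO4 and ZBTB10 also lost it without the 8 arrays (-0.80 and 0.90).

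In group means, mitochondrial genes were lower in total RNA with PP242: 60 of 64 OXPHOS genes lay below 0 with a median of -0.44 (camera adjusted p = 2.67e-18). Over all genes 0 passed and adjusted over the list alone 9 fell, among them the mitochondrial ribosomal proteins MRPL12 (-1.27 ± 0.31), MRPS7 (-1.23 ± 0.27) and MRPL47 (-0.92 ± 0.27) and the complex I subunit NDUFB3 (-0.89 ± 0.24). DNA replication genes had 52 of 53 below 0 (median -0.88, adjusted p = 1.62e-12) and histones 23 of 23 (-0.62, adjusted p = 1.78e-06). Both were called with each array left out and without the 8 (-0.53 and -0.46). DNA replication stood at -0.53 without PP242 3 too, and histones at -0.92 without PP242 1. Yet PP242 1 alone stood at -0.165 and -0.182, within the DMSO arrays (-0.338 to 0.265 and -0.364 to 0.229), PP242 2 at -0.885 and -0.808 and PP242 3, of the 8, at -1.542 and -1.236. Ribosomal proteins stood at -0.31 (adjusted p = 3.7e-10) and ribosome biogenesis genes at -0.30 (adjusted p = 1.32e-07), where MRTO4 fell over all genes and RRP1B (-0.84) and NHP2 (-0.64) fell with it adjusted over the list alone. Using an estimated correlation the adjusted p of these 5 lists ran from 0.759 to 0.945. Without PP242 2, with the smallest SD of all, 2.04, ribosomal proteins stood at -0.09 and ribosome biogenesis at -0.10, neither called. OXPHOS genes (-0.26) kept the call. Ribosome biogenesis stood at -0.45 without DMSO 2 and -0.46 without PP242 3. In PP242 2 endothelial, leukocyte and fibroblast marker medians were 0.39, 0.33 and 0.23 against the DMSO mean.

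In the same RNA, glycolysis genes had a median of -0.23 (camera adjusted p = 0.000107), with PGAM1, PFKFB3 and GAPDH lower adjusted over the list alone at -1.21, -0.56 and -0.44. Recombination genes stood at -0.32 (adjusted p = 0.000129), other DNA repair genes at -0.31 (adjusted p = 8.93e-06), with the glycosylase MBD4 lower adjusted over the list alone (-0.77), and checkpoint genes at -0.22 (adjusted p = 0.000799), with PPM1D lower (-0.92). Unfolded protein response and chaperone genes stood at -0.20 (adjusted p = 0.00175): adjusted over the list alone the chaperones DNAJB1 (-1.07) and HSPE1 (-0.61) and the endoplasmic reticulum protein SDF2L1 (-0.65) fell and ERN1 rose (0.70). Without PP242 2 these medians were -0.13, -0.22, -0.20, -0.12 and -0.04, none of them called, and the chaperone call ended also without DMSO 3 (-0.11). Among kept calls, glycolysis and chaperone genes stood at -0.37 and -0.32 without PP242 1, chaperone genes at -0.37 without PP242 3, and both repair lists at -0.19 without DMSO 3. FOXO targets stood at 0.22 (adjusted p = 0.00563), with CCNG2 higher over all genes and KLHL24 (1.06) and RICTOR (0.69) adjusted over the list alone. That call ended without DMSO 2 (0.06), PP242 1 (0.12) or 3 (0.04), and the 8 arrays (0.04). With an estimated correlation the adjusted p of these 6 lists ran from 0.676 to 0.945. Under quantile normalization the glycolysis, checkpoint and chaperone calls ended. In the uncalled leukocyte list TYROBP passed adjusted over the list alone (0.46).

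For translational efficiency with PP242, TOP messages moved down. The 23 other TOP mRNAs had 21 below 0 and a median of -0.25 (camera adjusted p = 1.6e-07), and ribosomal proteins had 44 of 48 below 0 and a median of -0.23 (adjusted p = 1.1e-06). Over all genes 0 members passed, and adjusted over the list alone NAP1L1 (-0.98 ± 0.30) and EIF2S3 (-0.79 ± 0.21) fell and 0 ribosomal proteins passed. OXPHOS genes had 53 of 64 above 0 (median 0.26, adjusted p = 1.02e-08) and chaperone genes 28 of 31 (0.22, adjusted p = 0.000237). At an estimated correlation the adjusted p of the 4 lists ran from 0.896 to 0.945. Without PP242 total 2 the ribosomal protein median was -0.50, and OXPHOS (0.10) and chaperone genes (-0.01) were not called. The ribosomal protein call ended without PP242 total 1 (-0.16) or 3 (-0.12), and stood at -0.14 and -0.39 without PP242 polysome 2 or 3. Other TOP mRNAs, called throughout, stood at -0.45 without PP242 polysome 3 and at -0.48 and -0.14 without PP242 total 2 or 3. OXPHOS genes stood at 0.40 without PP242 total 1, and chaperone genes at 0.34 without it and 0.12 without PP242 polysome 3. In limma 0 genes passed, and 341 had an unadjusted p under 0.05; after EIF2S3 the lowest p was that of the deadenylase PARN (0.76 ± 0.20, adjusted p = 1).

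With RAD001 no gene passed. In polysome RNA all 48 ribosomal proteins lay below 0 (median -0.28, camera adjusted p = 2.32e-15), and all 23 histones (median -0.78, adjusted p = 3.67e-13). Sterol and fatty acid synthesis genes had 26 of 27 above 0 (median 0.53, adjusted p = 2.31e-08), FOXO targets stood at 0.27 (adjusted p = 0.00016) and apoptosis regulators at -0.20 (adjusted p = 0.000666). Adjusted over the list alone KLHL24 rose (0.94 ± 0.27) and SESN1, also a p53 target, fell (-0.38 ± 0.11). These 5 lists held with each array left out. Values were -0.43 to -0.20, -1.10 to -0.30, 0.19 to 0.76, 0.12 to 0.30 and -0.25 to -0.14. RAD001 3 gave the -0.43, -0.30, 0.19 and 0.12. For sterol genes only RAD001 3 (1.227), of the 8, lay above the DMSO arrays (-0.192 to 0.291). The apoptosis call ended under quantile normalization. OXPHOS genes (-0.20, adjusted p = 5.27e-05) lost the call without RAD001 2 (-0.11) and stood at -0.12 without DMSO 1. Under an estimated correlation the adjusted p of the 6 lists ran from 0.875 to 0.945. NR1D2, a circadian nuclear receptor, and GEMIN6 had the lowest p under the naming rule, at 0.73 ± 0.17 and -0.52 ± 0.12 (limma adjusted p = 1, n = 3). HBP1, which the rule passes over, had a lower p, at 1.15 ± 0.25 (adjusted p = 1).

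DNA replication genes (median -0.55, adjusted p = 6.39e-09), mitosis genes (-0.39, adjusted p = 2.43e-07) and ATF4 targets (0.14, adjusted p = 0.0381) were called in polysome RNA with RAD001 and moved with the 8 arrays. Given an estimated correlation their adjusted p were 0.945, 0.945 and 0.999. Without RAD001 3 they stood at -0.06, -0.01 and 0.02, none of them called, and the ATF4 call also ended without DMSO 1 (0.09) or 3 (0.11). Without RAD001 2 mitosis genes stood at -0.60, and ATF4 targets stood at 0.25 and 0.22 without DMSO 2 or RAD001 1. By limma 0 genes passed in polysome RNA, total RNA and translational efficiency, and 488, 1707 and 425 had an unadjusted p under 0.05. In total RNA 25 passed without DMSO 2, 53 with array weights and 4, all lower, under quantile normalization.

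In total RNA with RAD001, DNA replication genes stood at -0.66 with 52 of 53 below 0 (camera adjusted p = 9.71e-08), and at -0.26 without the 8 arrays, called. That value rests on RAD001 2 (-0.542), since RAD001 1 (-0.043) lay within the DMSO arrays. RAD001 2 had the second smallest SD (2.196), endothelial, fibroblast and leukocyte marker medians of 0.204, 0.173 and 0.10 against the DMSO mean, and OXPHOS and ribosome biogenesis medians of -0.532 and -0.520. Ribosome biogenesis genes stood at -0.31 (adjusted p = 4.94e-07), where 0 passed over all genes and 4 fell adjusted over the list alone, the chaperone GRWD1 (-1.27 ± 0.33), MRTO4 (-0.90 ± 0.15), the methyltransferase FBL (-0.65 ± 0.18) and PES1 (-0.48 ± 0.14). MRTO4 had the lowest p over all genes (limma adjusted p = 0.0646), followed by the cytochrome oxidase assembly factor COA3 (-1.05 ± 0.19, adjusted p = 0.0786). OXPHOS genes stood at -0.26 (adjusted p = 1.88e-07), with MRPL12 lower adjusted over the list alone (-1.25), histones at -0.65 (adjusted p = 9.86e-06), p53 targets at -0.10 (adjusted p = 0.0371) and nuclear-retained RNAs at 0.29 (adjusted p = 0.0058). KLHL24 was higher adjusted over the list alone (1.01). Using an estimated correlation the adjusted p ran from 0.653 to 0.945. Without RAD001 2 ribosome biogenesis stood at -0.18, OXPHOS at -0.12 and p53 targets at -0.07, and without RAD001 3 histones stood at -0.33, none of them called. The p53 call also ended without RAD001 1 (-0.05), DMSO 1 or 3 (-0.11 each), under quantile normalization and with the low-level filter, and that of nuclear-retained RNAs without DMSO 2 (0.26) or RAD001 1 (0.25). Among kept calls, DNA replication stood at -1.01 and -0.26 without RAD001 1 or 3, nuclear-retained RNAs at 0.50 and 0.08 without RAD001 2 or 3, and p53 targets at -0.23 and -0.27 without DMSO 2 or RAD001 3.

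Translational efficiency with RAD001 was lower for ribosomal proteins (median -0.16, 37 of 48 below 0, camera adjusted p = 0.000954) and nuclear-retained RNAs (-0.21, adjusted p = 0.0168) and higher for glycolysis genes (0.21, 33 of 38 above 0, adjusted p = 0.00305). With an estimated correlation the adjusted p were 0.999, 0.834 and 0.896. The ribosomal protein call ended without RAD001 polysome 2 (-0.06) or RAD001 total 1 (-0.06) or 3 (-0.09), and the glycolysis call without DMSO polysome 1 (0.21) or RAD001 total 2 (0.11). That of nuclear-retained RNAs ended without DMSO total 2 (-0.22), RAD001 polysome 2 (-0.11) or RAD001 total 1 (-0.18) or 3 (-0.09). Among kept calls, ribosomal proteins stood at -0.09, -0.32 and -0.29 without DMSO polysome 1, RAD001 polysome 3 or RAD001 total 2, and nuclear-retained RNAs at -0.12, -0.46 and -0.44 without RAD001 polysome 1, polysome 3 or total 2. The lowest p were those of SMIM10 (0.66 ± 0.20) and PPP4R3C (0.57 ± 0.16).

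For PP242 with IR against DMSO in polysome RNA the falls were again in ID3 (-2.56 ± 0.40; 5.89 ± 0.49 against 8.45 ± 0.40, SD, n = 3; limma adjusted p = 0.00434), EDN2 (-1.69 ± 0.29), SMAD7 (-1.56 ± 0.27), SMAD6 (-1.54 ± 0.29), PMEPA1 (-1.33 ± 0.21) and SKIL (-1.19 ± 0.16, adjusted p = 0.00137). The rises were in IRAK2 (1.30 ± 0.19), DMBT1 (1.24 ± 0.25), PIM3 (1.13 ± 0.21) and EFNA1 (1.08 ± 0.16), with HBP1 (1.59 ± 0.25), chosen after its values were seen. In all 21 genes passed, 6 higher and 15 lower; under quantile normalization 55 passed, 32 higher and 23 lower. The count was 5, 13 and 9 without DMSO 1, 2 or 3 and 18, 7 and 4 without replicate 1, 2 or 3. EFNA1, IRAK2 and SKIL kept the call with each array left out. ID3 lost it without replicate 3 (-2.28), PMEPA1 without that array (-1.26) or DMSO 1 (-1.24), EDN2 (-1.90 to -1.31) without DMSO 2 or replicates 2 or 3, SMAD7 (-1.65 to -1.43) without DMSO 1 or 3 or replicate 3, SMAD6 (-1.67 to -1.41) and DMBT1 (1.05 to 1.52) without DMSO 1 or 3 or replicates 2 or 3, and PIM3 (1.00 to 1.21) without any array but replicate 1. DMBT1 and PIM3 did not pass without the 8 arrays (1.18 and 1.00).

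Among gene groups in polysome RNA with PP242 and IR, 47 of 48 ribosomal proteins lay below 0 (median -0.38, camera adjusted p = 1.7e-20), and adjusted over the list alone 10 fell, among them RPS19 (-1.12), RPL29 (-0.80), RPL26 (-0.67) and RPS10 (-0.60), with 0 over all genes. Other TOP mRNAs had 22 of 23 below 0 (-0.28, adjusted p = 1.09e-09). EIF2S3 (-0.78 ± 0.15) and the RNA-binding protein YBX1 (-0.66 ± 0.13) fell over all genes (limma adjusted p = 0.033 each) and 4 adjusted over the list alone, with NAP1L1 (-0.63) and EEF1D (-0.28). NF-kB genes stood at 0.19 (adjusted p = 1.63e-06), where LIF (3.00 ± 0.76), the feedback inhibitors TNFAIP3 (1.67 ± 0.52) and NFKBIA (0.68 ± 0.21) rose adjusted over the list alone. FOXO targets stood at 0.29 (adjusted p = 3.37e-06), where KLHL24 (1.13), the ubiquitin ligase FBXO32 (0.88), RICTOR (0.71) and CCNG2 (0.51) rose and 1 member fell on the same adjustment. Histones stood at -0.61 (adjusted p = 6.49e-06) with H1-3 lower adjusted over the list alone (-1.58). At an estimated correlation the adjusted p of these 5 lists ran from 0.653 to 0.945. All 5 were called with each array left out. Without replicate 2 ribosomal proteins stood at -0.22, without replicate 3 FOXO targets at 0.13 and histones at -0.18, without replicate 1 histones at -0.91, and without DMSO 3 NF-kB genes at 0.12. YBX1 (-0.75 to -0.58) lost its call without any array but DMSO 2 and EIF2S3 (-0.85 to -0.69) without each of the 6, and neither passed without the 8 (-0.70 and -0.85).

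DNA replication genes (median -0.68, adjusted p = 1.32e-08) and immediate early genes (0.36, adjusted p = 2.57e-05) moved with the 8 arrays: without replicate 3 they stood at -0.14 and 0.12, neither called. Lysosome and autophagy genes stood at 0.15 (adjusted p = 0.0054) and lost the call without DMSO 1 (0.13). Under an estimated correlation these 3 lists and the checkpoint list had an adjusted p of 0.945. Immediate early genes stood at 0.55 without replicate 2. Checkpoint genes had 30 of 39 members below 0 and a median of -0.35 (adjusted p = 0.00032), which was -0.05 and not called without replicate 3 or without the 8 arrays. Adjusted over the list alone RNF8 (-0.71) and the clamp subunit RAD1 (-0.53) fell, and the ubiquitin ligase RNF169 (0.65) and WDR48 (0.60) rose. On the same adjustment SESN1 fell (-0.40), PFKFB3 fell (-0.77) and ERN1 rose (0.81).

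In total RNA, where the combination of PP242 and IR had 2 arrays, 6 genes passed, 5 higher and 1 lower. ID3 fell to 5.67 ± 0.02 (SD, n = 2) from 8.19 ± 0.77 (n = 3), or -2.52 ± 0.45 (limma adjusted p = 0.0245). ZBTB10 (1.33 ± 0.20), the glucosylceramide synthase UGCG (0.89 ± 0.15) and CCNG2 (0.83 ± 0.14) rose, as did HBP1 (1.63 ± 0.28). SNORA28, a small nucleolar RNA, passed at 5.36 ± 0.19 against 3.65 ± 0.19, a level below the lower quartile of each DMSO array and not shown above background, so no fold is given; the low-level filter removes it. Both were chosen after their values were seen. The count was 1, 7 and 0 without DMSO 1, 2 or 3 and 6 and 0 without replicate 1 or 2, and under quantile normalization it was 12, 6 each way. With 1 array left out in turn, ID3 (-2.86 to -2.10), UGCG (0.78 to 0.99) and CCNG2 (0.68 to 0.97) lost the call with every array but DMSO 2, and ZBTB10 (1.17 to 1.49) without DMSO 3 or either array of the combination, and 0 genes passed without the 8. FOXO targets stood at 0.18 (camera adjusted p = 5.36e-06), with CCNG2 higher over all genes and KLHL24 (1.48) and RICTOR (0.87) adjusted over the list alone, and kept the call with each array left out. NF-kB genes stood at 0.18 (adjusted p = 0.000115), DNA replication genes at -0.76 (adjusted p = 1.32e-07) and histones at -0.68 (adjusted p = 1.83e-05). Given an estimated correlation the adjusted p of the 4 lists ran from 0.653 to 0.945. Without replicate 2, among the 8 arrays, DNA replication stood at -0.05 and histones at -0.11, and without replicate 1 NF-kB genes stood at -0.01, none of them called. Among kept calls, FOXO targets and NF-kB genes stood at 0.39 and 0.53 without replicate 2, FOXO targets at 0.33 without DMSO 3, NF-kB genes at 0.29 without DMSO 1, and DNA replication and histones at -1.54 and -1.25 without replicate 1. ERN1 was higher adjusted over the list alone (0.90).

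Translational efficiency with PP242 and IR was lower for 45 of 48 ribosomal proteins (median -0.46, camera adjusted p = 2.45e-14) and for 22 of 23 other TOP mRNAs (-0.48, adjusted p = 3.82e-14). Using an estimated correlation the adjusted p were 0.923 and 0.653, and both lists were called with each array left out (-0.60 to -0.30 and -0.67 to -0.30), both -0.30 without polysome replicate 2. Adjusted over the list alone NAP1L1 (-1.33 ± 0.31), EIF2S3 (-0.92 ± 0.22) and YBX1 (-0.72 ± 0.19) fell. In limma 0 genes passed, and 495 had an unadjusted p under 0.05; NAP1L1 and EIF2S3 also had the lowest p under the naming rule (adjusted p = 1).

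With RAD001 and IR in polysome RNA, all 23 histones lay below 0 with a median of -0.91 (camera adjusted p = 1.55e-20), and H1-3 fell adjusted over the list alone, at 3.95 ± 0.35 against 6.03 ± 0.22 (SD, n = 3; limma adjusted p = 0.541 over all genes). Mitosis genes had 50 of 51 below 0 (median -0.63, adjusted p = 6.12e-18), DNA replication genes stood at -0.52 (adjusted p = 4.48e-09) and ribosomal proteins at -0.11 (adjusted p = 0.00175). With an estimated correlation the adjusted p were 0.653, 0.923, 0.945 and 0.999. These groups moved with the 8 arrays: without them, histones stood at -0.54 and mitosis genes at -0.17, both called, and DNA replication genes at 0.00, not called, as without replicate 3 alone (0.00), where histones and mitosis genes stood at -0.54 and -0.17 and ribosomal proteins at -0.22, called. Ribosomal proteins lost the call without DMSO 1 or replicates 1 or 2 (-0.05 each) and under quantile normalization. EFNA1 had the next lowest p (0.78 ± 0.16, adjusted p = 0.541), and KLHL24 was higher adjusted over the list alone (0.99). By limma 0 genes passed, and 529 had an unadjusted p under 0.05.

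In total RNA with RAD001 and IR, 2 genes passed. The GTPase RAB20 fell from 6.78 ± 0.21 to 5.76 ± 0.05 (SD, n = 3 each; -1.01 ± 0.17, limma adjusted p = 0.0418), and SNORA28, chosen after its values were seen, passed at 5.13 ± 0.05 against 3.65 ± 0.19 in DMSO (adjusted p = 0.0484), again not shown above background, and not with the low-level filter. The count was 3 without DMSO 2 and 0 without any other of the 6 arrays, without the 8 and under quantile normalization. RAB20 ranged from -1.09 to -0.89 and kept its call only without DMSO 2. Histones stood at -0.64 (camera adjusted p = 7.26e-07), with H1-3 lower adjusted over the list alone (3.64 against 5.44), mitosis genes at -0.51 (adjusted p = 8.34e-07) and DNA replication genes at -0.43 (adjusted p = 0.00236). Nuclear-retained RNAs stood at 0.49 (adjusted p = 0.000818), with FTX higher adjusted over the list alone (1.12 ± 0.35). At an estimated correlation the adjusted p ran from 0.653 to 0.999. Without replicate 3, among the 8 arrays, histones stood at -0.35, mitosis genes at -0.09 and DNA replication genes at 0.04, none of them called; the last also lost the call without DMSO 3 (-0.29). Nuclear-retained RNAs stood at 0.30 without replicate 1 or 3 and DNA replication at -0.65 without replicate 1, called. KLHL24 (1.02) and MRTO4 (-0.57) passed adjusted over the list alone.

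Translational efficiency with RAD001 and IR was lower for nuclear-retained RNAs (median -0.45, 8 of 10 below 0, camera adjusted p = 0.00494) and other TOP mRNAs (-0.14, 19 of 23 below 0, adjusted p = 0.00563). Under an estimated correlation the adjusted p were 0.653 and 0.945. The TOP call ended without polysome replicate 2 (-0.07) or total replicate 3 (-0.09) of the combination and under quantile normalization, and stood at -0.26 without polysome replicate 3. In limma 0 genes passed and 684 had an unadjusted p under 0.05, with TAAR1 (1.13 ± 0.29) and RAB20 (0.93 ± 0.23) lowest in p.

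Set directly against each other, the inhibitors differed in SKIL, a repressor of SMAD proteins. Its polysome level was 10.70 ± 0.12 with PP242 and 11.98 ± 0.14 with RAD001 (SD, n = 3), a difference of -1.27 ± 0.16 (limma adjusted p = 0.000358), and in total RNA the difference was -1.30 ± 0.16 (adjusted p = 0.000258). With IR it was -1.28 ± 0.16 in polysome RNA (adjusted p = 0.000328) and -0.99 ± 0.18 in total RNA, which did not pass (adjusted p = 0.167). SKIL kept these 3 calls with each array left out, but not without the 8 arrays in total RNA (-1.28) or in polysome RNA with IR (-1.29). Doses are not given. In polysome RNA without IR 6 genes passed, 1 higher and 5 lower with PP242. The helix-loop-helix repressor MSC (-1.92 ± 0.35) and PMEPA1 (-1.22 ± 0.21) were lower and the tumour suppressor RASSF1 higher (0.46 ± 0.08). ID4 (-1.03 ± 0.19) and EIF2S3 (-0.83 ± 0.15), also lower, were chosen after their values were seen. The count was 2, 1 and 4 without PP242 1, 2 or 3 and 1, 1 and 6 without RAD001 1, 2 or 3. MSC (-2.01 to -1.76) lost the call without each of the 6 arrays, and PMEPA1 (-1.41 to -1.09) and RASSF1 (0.41 to 0.52) without any but RAD001 3. RASSF1 lost it under quantile normalization, and MSC (-2.09), RASSF1 (0.47), ID4 (-1.18) and EIF2S3 (-0.98) lost it without the 8. SKIL was the 1 gene that passed in total RNA, where the count was 3 and 7 without PP242 1 or 3 and 2 without RAD001 2, and in polysome RNA with IR, where it was 3 without RAD001+IR 3. In total RNA with IR 0 genes passed by limma, 648 had an unadjusted p under 0.05, and ZNF165 (0.74 ± 0.14) was second to SKIL in p; 1 gene passed without PP242+IR 1.

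Ribosomal proteins were lower with PP242 than with RAD001 in polysome RNA, with 45 of 48 below 0 and a median of -0.28 (camera adjusted p = 6.75e-14), and with 46 of 48 below 0 and a median of -0.29 when both were given with IR (adjusted p = 8.1e-18). Other TOP mRNAs stood at -0.27 (adjusted p = 5.49e-11) and -0.25 (adjusted p = 1.43e-10); EIF2S3 passed over all genes without IR, though not without the 8, and adjusted over the list alone 5 and 4 members fell. Mitosis genes, which had 47 of 51 members above 0 in both comparisons, stood at 0.32 (adjusted p = 2.13e-08) and 0.50 (adjusted p = 4.26e-15), and NF-kB genes at 0.19 without IR (adjusted p = 1.87e-05). Given an estimated correlation the adjusted p ran from 0.921 to 0.984. The mitosis calls ended without RAD001 3 (-0.06) and without RAD001+IR 3 (0.04), while without all 8 arrays they stood at 0.33 and 0.46 and were called. Without PP242 1, 2 or 3 or RAD001 2 mitosis genes stood at 0.14, 0.09, 0.70 and 0.51, and with IR at 0.31, 0.26 and 0.90 without replicates 1, 2 or 3 of PP242+IR. Ribosomal proteins stood at -0.18 and -0.15 without PP242 2 or RAD001 3, and with IR at -0.12 and -0.17 without replicate 2 of PP242 or 3 of RAD001. Other TOP mRNAs stood at -0.15, -0.17 and -0.15 without PP242 1 or 2 or RAD001 3, and with IR at -0.14, -0.42 and -0.14 without replicates 2 or 3 of PP242 or 3 of RAD001. NF-kB genes stood at 0.08 without PP242 1.

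Against IR alone, PP242+IR lowered ID3 in polysome RNA by -2.36 ± 0.40 (5.89 ± 0.49 against 8.25 ± 0.57, SD, n = 3; limma adjusted p = 0.0105), SMAD7 by -1.60 ± 0.27 and SKIL by -1.14 ± 0.16 (adjusted p = 0.0028). DMBT1 (1.38 ± 0.25), the matrix protein TINAGL1 (1.09 ± 0.21) and PIM3 (1.07 ± 0.20) rose. In all 29 genes passed, 13 higher and 16 lower. The count was 7, 12 and 1 without IR 1, 2 or 3 and 10, 15 and 5 without replicate 1, 2 or 3, and 11 without the 8 arrays, where ID3 (-2.07), DMBT1 (1.32) and PIM3 (0.94) did not pass. SKIL kept its call with each array left out; TINAGL1 (0.96 to 1.16) and PIM3 (0.94 to 1.17) lost it without each of the 6, DMBT1 (1.2 to 1.55) without IR 1 or 3 or replicates 2 or 3, SMAD7 (-1.74 to -1.47) without IR 1 or 3 or replicate 3 and ID3 without IR 3 (-2.04) or replicate 3 (-2.07). Ribosomal proteins and other TOP mRNAs both had a median of -0.26 (camera adjusted p = 4.52e-11 and 1.22e-09), with 0 and 2 members lower over all genes and 1 and 4 adjusted over the list alone. Using an estimated correlation both had an adjusted p of 0.921. Without replicate 2 they stood at -0.13 and -0.17 and without replicate 3 at -0.40 and -0.44.

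In total RNA, PP242+IR against IR passed 6 genes, 4 higher and 2 lower. ID3 (-2.67 ± 0.45) and SMAD7 (-1.64 ± 0.30) fell and ZBTB10 (1.2 ± 0.20) and CCNG2 (0.87 ± 0.14) rose, with limma adjusted p of 0.0161 to 0.0349. HBP1 (1.59 ± 0.28) and SNORA28 (5.36 against 3.50 in IR, removed by the filter), also higher, were chosen after their values were seen. The count was 4, 5 and 0 without IR 1, 2 or 3 and 0 without either array of the combination or without the 8. With 1 array left out in turn, SMAD7 (-1.88 to -1.41) lost the call 5 times of 5, CCNG2 (0.72 to 1.01) with every array but IR 2, and ID3 (-2.93 to -2.25) and ZBTB10 (1.03 to 1.36) without IR 3 or either array of the combination.

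RAD001+IR against IR passed 0 genes in polysome RNA by limma, where 657 had an unadjusted p under 0.05, and 1 in total RNA. Camera called 10 lists in polysome RNA and 9 in total RNA, which are not described. NR1D2 (0.87 ± 0.17, limma adjusted p = 0.66, n = 3) and MBD3L1 (0.58 ± 0.14) had the lowest p in polysome RNA. The gene in total RNA was SNORA28 (5.13 ± 0.05 against 3.50 ± 0.18, below the lower quartile of each IR array; adjusted p = 0.022), chosen after its values were seen. With the low-level filter 0 passed; the count was 3 without IR 1 and 0 without any other of the 6 arrays or without the 8. The lipid droplet protein PLIN2 (-0.64 ± 0.12) and TSEN54 (-0.60 ± 0.12) followed in p (adjusted p = 0.134).

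Whether IR acts differently with an inhibitor was tested as an interaction. By limma 0 genes passed in polysome or total RNA, with 225 and 293 at an unadjusted p under 0.05 for PP242 and 146 and 205 for RAD001. The lowest p belonged to HRCT1 (0.60 ± 0.17) and SIAH2 (0.56 ± 0.16) for PP242 in polysome RNA, DCAF8L1 (-0.83 ± 0.23) and TYR (-0.65 ± 0.18) in total RNA, AKAIN1 (-0.73 ± 0.21) and NENF (0.62 ± 0.20) for RAD001 in polysome RNA, and SMIM10 (0.83 ± 0.20) and BAAT (-0.55 ± 0.17) in total RNA. For ribosomal proteins the IR effect was higher with PP242 than without by a median of 0.32 in polysome RNA (47 of 48 above 0, camera adjusted p = 4.74e-10) and 0.34 in total RNA (adjusted p = 2.3e-11). With RAD001 the medians were 0.32 (48 of 48, adjusted p = 2.95e-12) and 0.16 (adjusted p = 0.000168). OXPHOS genes stood at 0.26 (adjusted p = 1.12e-06) and 0.22 (adjusted p = 1.72e-06) with PP242 and at 0.31 (adjusted p = 1.83e-08) and 0.12 (adjusted p = 0.00155) with RAD001. With an estimated correlation the adjusted p were 0.921 for the 6 tests of PP242 and of RAD001 in polysome RNA and 1 for the 2 of RAD001 in total RNA. The polysome calls held with each array left out. In total RNA, PP242 2 ended both PP242 calls (0.17 and 0.05) and IR 1 the second (0.13). For RAD001 the total RNA calls ended without IR 1 (0.05 and -0.02), RAD001 2 (0.01 and -0.04) or RAD001+IR 1 (0.14 and 0.02), and 1 each without RAD001+IR 3 (ribosomal proteins, 0.07) and DMSO 3 (OXPHOS, 0.05). Both OXPHOS calls in total RNA ended under quantile normalization. Kept calls of ribosomal proteins stood at 0.20 without PP242 polysome 2, 0.50 and 0.14 without PP242+IR polysome 2 and 3, 0.20 and 0.21 without IR total 1 or PP242+IR total 2, 0.19 without RAD001+IR polysome 3, and 0.27 and 0.32 without RAD001 total 1 or RAD001+IR total 2. Those of OXPHOS genes stood at 0.15 and 0.14 without PP242+IR polysome 1 or total 1, 0.37 without PP242 total 1, and 0.23, 0.21, 0.27 and 0.25 without IR total 2, DMSO total 2, RAD001 total 1 or RAD001+IR total 2.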

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

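The tests of array quality, of other cell types with the genes named beside it, of DNA replication without the 8 arrays and of ribosomal proteins in total RNA, and all counts of splits, were chosen after the results were seen. The interaction lists below were called at the preset correlation, none at an estimated one. Both inhibitors share the IR and DMSO arrays, so their values are not independent. Ribosomal proteins differed by 0.32 in polysome RNA and 0.336 in total RNA with PP242, and by 0.323 and 0.159 with RAD001. In that order OXPHOS genes differed by 0.262, 0.216, 0.313 and 0.116. Probe sets without a gene name, which the comparisons of genes did not use, also passed in limma over every probe set. There were 8 (1 higher) for PP242 in polysome RNA, 6 (2 higher) for PP242 in total RNA, 1 (lower) for PP242+IR in polysome RNA and 4 (all higher) for RAD001+IR in total RNA. Against IR, 1 (higher) passed for PP242+IR in polysome RNA and 1 (lower) for RAD001+IR in total RNA.

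The 8 arrays separated on the second principal component (24.8% of the variance), at 30.46 or above against -1.18 or below in the other 27. Array quality is open: all 8 had a median and SD within the range of other arrays, which normalization may set. RNA of fibroblasts, leukocytes or endothelial cells is argued against, since no marker list rose by over 0.22. These lists would miss another epithelial culture or line, which stays open. In polysome RNA the cadherin CDH2 stood at 7.04 to 7.14 in 4 of the 8 against 9.06 to 9.91 in the other 14, CAV1 at 10.91 to 11.28 against 12.37 to 13.08 and CDH1 at 13.51 to 13.88 against 12.05 to 13.40, and their ranges were apart in total RNA too, while those of KRT5, EPCAM and VIM overlapped. A stronger response to the inhibitor is also argued against, because the shift correlated across genes with the effect in other arrays at a median r of 0.07 (-0.04 to 0.16), while shifts of different groups correlated at 0.88 to 0.94. A separate batch without controls of its own cannot be told apart from a difference between replicates. No other biological explanation was tested.

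Lower DNA replication genes in polysome RNA may come from these arrays. Without the 8, the median was 0.00 with RAD001 and IR, so they account for that fall. It was -0.06 with RAD001, -0.20 with PP242 and -0.14 with PP242+IR, uncalled without replicate 3 alone, which leaves these open. No other biological explanation was tested.

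Lower ribosomal protein mRNAs on polysomes with PP242 (-0.53) could reflect compression of bright probe sets, since their mean level was 11.28 against 6.18 for all genes. Of 10000 random lists matched on mean level, 0 had a median as low (-0.33 to 0.08), which argues against it. A lower mRNA level alone cannot be told apart from lower loading. Translational efficiency was -0.23 with all arrays and -0.50 without PP242 total RNA replicate 2, but -0.14 without PP242 polysome replicate 2, and -0.16 and -0.12 without PP242 total RNA replicates 1 or 3, which ended the call, as an estimated correlation did.

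Splits of the same arrays were counted, the real one included. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, so only the real count and the highest of the other splits are given. For genes these were 60 and 0 for PP242 in polysome RNA, 21 and 0 for PP242+IR, 29 and 0 for PP242+IR against IR, 6 and 1 for PP242 against RAD001 and 1 and 0 for that pair with IR. In total RNA they were 2 and 0 for RAD001+IR and 1 and 0 for it against IR. For PP242 in total RNA they were 28 and 874 (2 splits as large), and for PP242 against RAD001 there 1 and 3734 (5 as large), which points to a structure of the samples. The 874 came from DMSO replicates 1 and 3 with PP242 replicate 1, and the 3734 from PP242 replicates 1 and 2 with RAD001 replicate 2. Where the real count was 0, every split is as large by construction (10 of 10), which says nothing of chance. There the highest other was 14 for RAD001 and 1 for IR in total RNA and 0 in the polysome comparisons of IR, RAD001, and RAD001+IR against DMSO or IR. For called lists, adjusted within each comparison, the real count and highest other were 6 and 8 for IR, 15 and 13 for PP242, 14 and 16 for RAD001, 14 and 17 for PP242+IR and 13 and 17 for RAD001+IR in polysome RNA. The splits as large numbered 6, 1, 4, 4 and 5. In total RNA they were 0 and 15 for IR, 16 and 19 for PP242, 16 and 16 for RAD001 and 11 and 14 for RAD001+IR, with 10, 7, 3 and 6 splits as large. The same holds for the 100 of 100 drawn splits of translational efficiency and interactions, which were not drawn for comparisons with the group of 2 arrays. The highest other was 0, 3, 5 and 1 for IR, PP242, RAD001 and RAD001+IR, 1 and 1 for the polysome interactions and 414 for that of RAD001 in total RNA, again a structure of the samples.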

How the results depend on the processing

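Fits without the 8 arrays that stand apart, the batch term for them, and leaving out arrays in the interactions were chosen after the results were seen. Counts are genes past the threshold; the cause of a changed count was not tested unless stated. Of 102 list results, 95 kept direction and call with the filter on low levels, 93 with the batch term, 89 without the 8 arrays and 84 under quantile normalization. Of 163 single-gene results 58 were called. All 58 lost the call when only the arrays compared were fitted, which leaves fewer arrays for the spread, 29 without the 8 arrays, 6 under quantile normalization and 1 with the batch term, and no gene turned. Counted once per result and array, leaving out 1 array ended 114 list calls, 7 of which turned, and 187 gene calls. Of 144 list calls, 0 held with an estimated correlation or fry and 3 were made by fry with the batch term.

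List results that turned in the direction of the test were chaperone genes with PP242 without PP242 total RNA replicate 2 (-0.04 in total RNA, range over left-out arrays -0.37 to -0.04, and -0.01 in translational efficiency, range -0.01 to 0.34), mitosis genes with RAD001 in polysome RNA with the batch term (0.01 by camera and fry), DNA replication with PP242 and IR in total RNA without replicate 2 of the combination (-0.05, range -1.54 to -0.05), and DNA replication with RAD001 and IR in total RNA without replicate 3 of the combination or the 8 arrays (0.04 each, range -0.65 to 0.04). In the RAD001 interaction in total RNA, ribosomal proteins stood at 0.01 without RAD001 replicate 2 (range 0.01 to 0.32), and OXPHOS genes at -0.02 without IR replicate 1 and -0.04 without RAD001 replicate 2 (range -0.04 to 0.27).

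Replicate numbers may pair arrays, which the main fit ignores: 28 of 35 correlated best with their own number. Of 187 same-number pairs 107 correlated above 0.1 (-0.63 to 0.94). With the replicate block, counts against DMSO were 174 for PP242 in polysome RNA and 95 in total RNA, and 59 and 33 for PP242+IR. PP242 against RAD001 gave 12 and 4, the same pair with IR 2 and 3, and PP242+IR against IR 61 and 21. The block ended no list or gene call.

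With array weights, counts against DMSO were 3 for IR in total RNA, 1079, 181 and 1 for PP242 in polysome RNA, total RNA and translational efficiency, 53 for RAD001 in total RNA, 185 and 34 for PP242+IR in polysome and total RNA, and 999 for RAD001+IR in total RNA. PP242 against RAD001 gave 240 in polysome RNA and with IR 12 and 1, PP242+IR against IR 323 in polysome RNA, and RAD001+IR against IR 2 and 3. PP242 total RNA replicate 2 had a weight of 0.1. DMSO total RNA replicate 1 had 7.06 against 0.44 and 0.84 for replicates 2 and 3, so weighted counts against DMSO in total RNA rest largely on 1 control array.

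With the threshold of the design text, p under 0.05 without adjustment and a larger fold, counts were 29 and 1 for PP242 in polysome RNA and translational efficiency, 1, 28 and 11 for RAD001 in polysome RNA, total RNA and translational efficiency, 43 and 7 for PP242+IR in total RNA and translational efficiency, and 4, 68 and 38 for RAD001+IR. PP242 against RAD001 gave 10 and 37, with IR 7 and 17. Against IR, total RNA gave 48 for PP242+IR and 53 for RAD001+IR. The interactions gave 1 and 9 for PP242 and 2 for RAD001 in total RNA.

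With the batch term, counts were 203 and 151 for PP242 in polysome and total RNA, 70, 13 and 1 for PP242+IR in polysome RNA, total RNA and translational efficiency, 1 and 0 for RAD001+IR, 41 and 11 for PP242 against RAD001, 23 and 12 for that pair with IR, 93 and 13 for PP242+IR against IR, and 0 for RAD001+IR against IR in total RNA. Its genes included all 60, 28 and 21 called with PP242 in polysome and total RNA and with PP242 and IR in polysome RNA. Without the 8 arrays, PP242+IR against IR gave 11 in polysome RNA, and 0 passed in total RNA for PP242+IR and RAD001+IR against DMSO or IR and for PP242 against RAD001, and in polysome RNA for that pair with IR. Of the 60, 28 and 21 genes, 33, 8 and 11 were called without them.

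Under quantile normalization, counts were 86 for PP242 and 4 for RAD001 in total RNA, 55 and 12 for PP242+IR, 0 for RAD001+IR in total RNA, 2 and 1 for PP242+IR against RAD001+IR and 53 and 14 for PP242+IR against IR. Over every probe set, where more are tested, they were 36 for PP242 and 10 for PP242+IR in polysome RNA, 1 for PP242+IR and 6 for RAD001+IR in total RNA, 1 for PP242 against RAD001 and 13 for PP242+IR against IR in polysome RNA, and 2 for RAD001+IR against IR in total RNA. The filter gave 1 and 0 for RAD001+IR in total RNA against DMSO and IR.

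Leaving out 1 array in turn gave 7 to 32 for PP242 in polysome RNA and 2 to 300 in total RNA, 0 to 25 for RAD001 in total RNA, 4 to 18 and 0 to 7 for PP242+IR, 0 to 3 for RAD001+IR in total RNA, 1 to 6 and 1 to 7 for PP242 against RAD001, 1 to 3 and 0 to 1 for that pair with IR, 1 to 15 and 0 to 5 for PP242+IR against IR, 0 to 3 for RAD001+IR against IR in total RNA, and 126 to 156 called lists. Signal over background was not analysed; the filter removes SNORA28 and, of genes named for a low p, AKAIN1, GNMT, RTL1, SMIM10, PPP4R3C, MBD3L1, DCAF8L1, TYR and BAAT.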

Other observations

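The genes and the list in this part were chosen after the results were seen, except that the bound for the SMAD test was written first. HAS2, which makes hyaluronan, stood at 14.14 ± 0.96 with PP242 and 11.19 ± 0.37 with DMSO in polysome RNA (SD, n = 3), a difference of 2.95 ± 0.73 that did not pass (limma adjusted p = 0.0881). FST, the activin antagonist follistatin, differed by 2.89 ± 0.72 (adjusted p = 0.0865). Without the 8 arrays the differences were 2.44 (adjusted p = 0.0146) and 2.27 (adjusted p = 0.0414). ID1, at -4.02 ± 0.93 with PP242 (adjusted p = 0.0635), stood at -3.17 (adjusted p = 0.0146) without them. SKIL fell in total RNA too, at 11 ± 0.52 against 12.14 ± 0.09 (-1.14 ± 0.16, adjusted p = 0.00126). With RAD001, SKIL stood 0.12 ± 0.16 from DMSO in polysome RNA.

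Lower ID3, SMAD6, SMAD7, SKIL and PMEPA1 with PP242 may reflect lower SMAD signalling, a hypothesis tested on 17 other SMAD targets. Their median change in polysome RNA was -0.01, and 46.5% of 10000 random lists matched on mean level were as low. The 17 gave no evidence for it. The median met the bound written first against it, above -0.1. Members ran from SMURF2 (-1.23) and BAMBI (-0.84) to CCN2 (1.49) (quartiles -0.36 and 0.11). ID1, ID2 and ID4 (-4.02, -0.74 and -1.17) were not among them. A condition that the lower quartile also lie above -0.1 was added after the value was seen. Only with it is the hypothesis left undecided rather than argued against. Of the 17, 0 passed in limma over all genes or adjusted over the list alone.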
